A study of Mus musculus with 6 samples.

How the data were processed

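Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with biotin-labelled cRNA made from 400 ng of total RNA of injured carotid arteries. Per the labels, 3 arrays held RNA of wild-type (WT) mice and 3 held RNA of mice lacking IRF4 in all tissues (IRF4 KO). Each array pooled 3 to 5 vessels taken 14 days after the operation, and the labels call the 3 samples of a genotype biological replicates. Arrays are named here by genotype and replicate number.

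The deposited values are log2 probe set intensities, 1 value per probe set and array. Per the submitters' processing notes they were made by the authors with Affymetrix Expression Console and RMA, a procedure that corrects the background, normalizes between arrays and summarises the probes of a set. Versions and settings are not given in the sources used here, and the image files were not analysed here. The table held 45101 probe sets, with array medians between 3.94 and 4.12 and values between 1.34 and 13.9. RMA pulls dim probe sets toward a common background level, so changes of weakly expressed genes are understated.

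Probe sets were named through the platform annotation that came with the data. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had no symbol there; 64 of the probe sets were Affymetrix controls. Only probe sets with 1 symbol entered the gene table. Symbols were checked through the Entrez number against a RefSeq table of the assembly GRCm38.p6, which held 34754 of those probe sets and changed 0 symbols. That table was used only for names and for which genes lie near Irf4. Each of the 18194 genes took the probe set with the highest mean over the 6 arrays; 9012 genes had more than 1 probe set. No dim gene was removed.

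IRF4 KO was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, statmod 1.5.0 installed), a two-sided moderated test on the log2 values with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 18194 genes. Changes are IRF4 KO minus WT on the log2 scale, values are means ± SD over 3 arrays per genotype, and SE is the moderated standard error. Gene lists were tested with limma's camera (inter-gene correlation 0.01, two-sided), adjusted over 26 lists. Members were also adjusted over the list alone, camera was repeated with an estimated correlation, and fry was run beside it. Of 407 list entries, 44 were not measured by a probe set of 1 gene. Genes within 20 Mb of Irf4 were compared with all others by Fisher's exact test, two-sided.

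The comparison, the lists and the rule for named genes were fixed before the data were examined. The rule named Irf4 and Klf4 always. It named the 10 higher and 10 lower genes with the largest change among genes past the threshold, with no overlap between genotypes and the higher mean above the median of all gene means (4.89). Symbols made of Gm or LOC and digits, symbols ending in Rik, Xist and Y-linked genes were left out. Places left over were filled by the smallest unadjusted p, which here filled all of them. It also named up to 4 members per list with the smallest p, and members that passed. Other genes are named here as chosen after their values were seen.

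The gene test was checked on data simulated for this comparison over 18194 genes, with 100 genes changed at each size. It recovered 19% of genes changed by 1 log2 unit and 74% of those changed by 2, called 9 unchanged genes, and called 0 genes when nothing was changed. With 1 list shifted by 0.5 log2 units, camera called 1 list, the shifted one. The simulated noise was independent between genes, and the genes changed singly were drawn from those above the median level. The check therefore does not show how camera behaves where genes vary together, as they do in these arrays. It also does not show how well changes of dim genes are recovered. The precision of each value is limited by the number of arrays.

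The alternatives were a replicate block, the mean of all probe sets of a gene, a filter on dim genes, array median subtraction, quantile normalization, a robust intensity trend, array weights, leaving out each array in turn, other thresholds, an estimated correlation, fry and a 5 Mb window. Several alternatives were added after seeing the data: a block for arrays with low poly-A spike-in controls and leaving those 2 arrays out (both also with an estimated correlation), leaving out genes with p under 0.001 from the lists, fry for the count of lists, and a fit on all probe sets. The poly-A controls (24 probe sets) are bacterial transcripts added to the RNA before labelling; the hybridisation controls (18 probe sets) are added later.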

Results

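The transcriptome of wire-injured mouse carotid arteries was measured in WT mice and in mice without IRF4, an interferon regulatory factor best known for its part in plasma cells, T cells and macrophages. In this injury a wire is passed through the artery to strip its endothelium, after which smooth muscle cells multiply and a neointima forms. The arteries were taken 14 days after injury, with 3 arrays per genotype and 3 to 5 vessels pooled on each. Pairwise correlations across probe sets ranged from 0.951 (WT 3 with IRF4 KO 3, and IRF4 KO 1 with IRF4 KO 3) to 0.990 (WT 2 with IRF4 KO 2), and at most 0.514% of the values of a pair of arrays were identical.

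The targeted gene was read first. The Irf4 probe set used for the gene gave 3.64 ± 0.26 in WT and 3.57 ± 0.26 in IRF4 KO (SD, n = 3), and the other gave 3.28 ± 0.30 and 3.19 ± 0.15. The gene's log2 change was -0.065 (SE 0.22, limma adjusted p = 0.999). Both probe sets lay below the median level of all genes, 4.89, in both genotypes, and the labels do not say which part of Irf4 was deleted. The Irf4 values therefore did not check the genotype labels, that of IRF4 KO 1 included.

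The main comparison asks how loss of IRF4 alters gene expression in the injured artery. Of the 26 genes with the smallest p, 18 were on the lists of smooth muscle, matrix, cell cycle, KLF, inflammatory and macrophage genes, and none of the 26 passed the threshold over all genes. Klf4, a transcription factor that represses the contractile genes of smooth muscle, read 8.01 ± 0.10 in WT and 6.87 ± 0.11 in IRF4 KO, a log2 change of -1.14 (SE 0.18). The cytokine gene Tnf read 3.85 ± 0.10 and 5.17 ± 0.13, a change of 1.31 (SE 0.18) from a WT level below the median of all genes. Acta2, which encodes smooth muscle actin, read 12.75 ± 0.12 and 13.89 ± 0.04, a change of 1.14 (SE 0.17) or 2.20-fold. Tgfb1, a growth factor gene, read 5.08 ± 0.06 and 3.95 ± 0.06, a change of -1.13 (SE 0.17). With limma, 0 of 18194 genes had an adjusted p under 0.05, and the smallest was 0.252, shared by Klf4, Tnf, Acta2 and Tgfb1.

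At an unadjusted p under 0.05 there were 271 genes, 74 higher and 197 lower in IRF4 KO, where chance alone would give 909.7. The genotypes did not overlap in 1033 genes (5.68%), where chance gives 10% for 3 arrays against 3. In contrast, 26 genes had p under 0.001 (15 higher, 11 lower), where chance would give 18.2, and no gene fell between 8.00e-04 and 0.00357. The sizes of change in these 26 genes lay between 0.90 and 1.55, with a median of 1.12, and 23 of them between 1 and 1.3. Their median SD within a genotype was 0.111, against 0.287 over all genes.

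Besides Tnf and Acta2, the 10 higher genes named by the rule were Ccnd1, Smtn, Cd86, Mmp2, Vcam1, Nos2, Tagln and Pcna. Ccnd1, a cyclin gene of the G1 phase, was higher by 1.15, and Pcna, the replication clamp, by 1.09. Cd86, a costimulatory molecule of antigen-presenting cells, was higher by 1.12. Besides Klf4 and Tgfb1, the 10 lower genes were Nnt, Rab4a, Cdkn1a, Tesc, Dpp10, Lcor, Ppp4r3b and Micu3. Nnt, a mitochondrial transhydrogenase, showed the largest change of the 20, from 9.08 ± 0.31 to 7.54 ± 0.28 (-1.55). Cdkn1a, a cell cycle inhibitor, changed by -1.15, and Rab4a, an endosomal GTPase, by -1.10. Dpp10 (-1.32), Lcor (-0.84), Ppp4r3b (-0.76) and Micu3 (-0.96) had adjusted p values of 0.999. With the mean of all probe sets of a gene these changes were smaller (-0.97, -0.16, -0.36 and -0.44), as were those of Nnt (-0.99), Rab4a (-0.83) and Tesc (-0.58).

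In the smooth muscle contractile list, 3 of 21 measured genes passed when adjusted over the list alone, and 0 passed over all genes. These were Acta2, Tagln (1.08) and Smtn (1.09), cytoskeletal genes of contractile smooth muscle. Their SDs within a genotype were at most 0.089, whereas the lowest among the other 18 members was 0.197. The origin of such small spreads stays open and is taken up under other observations. The smooth muscle myosin Myh11, named after its values were seen, read 11.83 ± 0.39 in WT and 12.03 ± 0.34 in IRF4 KO, and the calponin Cnn1 10.81 ± 0.33 and 10.76 ± 0.36. Pln, a regulator of the calcium pump, read 6.43 ± 0.24 and 5.87 ± 0.74. Of the 21 genes, 10 were higher and 11 lower in IRF4 KO. The list mean was 0.14 and camera called it up (adjusted p = 0.039), while its median was -0.014. The adjusted p was 0.833 with an estimated correlation. Without Acta2, Tagln and Smtn, the other 18 genes had a mean of -0.026 (adjusted p = 0.987). The 3 genes were left out for their small p in this same comparison, so that value cannot show that the rest is unshifted. The list mean was -0.12 between IRF4 KO 1 and WT 3 and 0.26 over the other 4 arrays, and the call ended without WT 1 (0.150), WT 3 (0.421), IRF4 KO 2 (0.738) or IRF4 KO 3 (0.304).

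**Figure D1:**
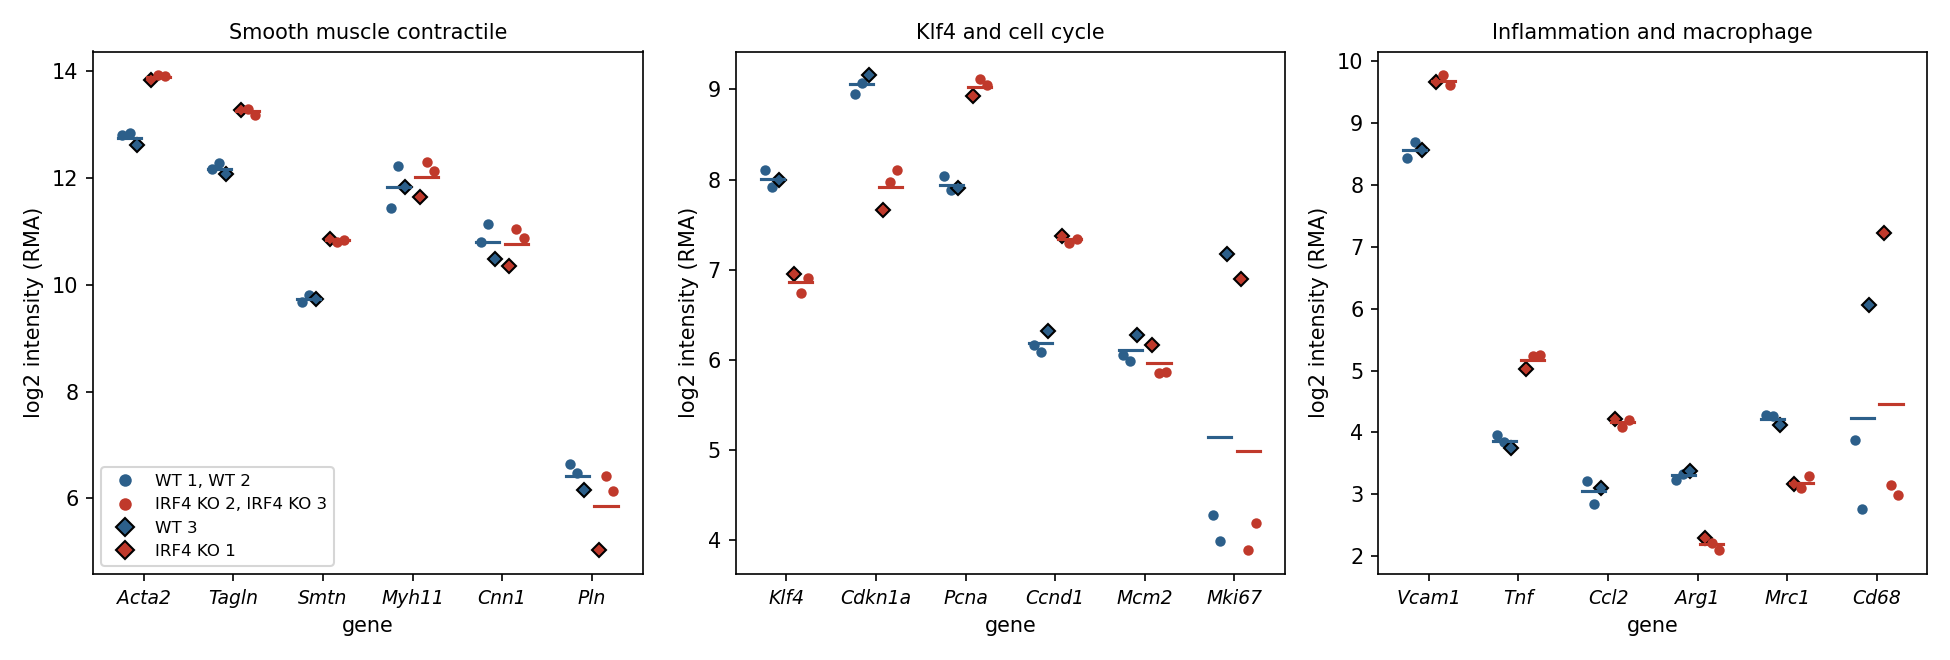
Log2 intensity per array (y axes) for genes of contractile smooth muscle, of the cell cycle with Klf4, and of inflammation and macrophages (x axes); points are arrays, bars are means of 3 arrays, blue is WT, red is IRF4 KO, and outlined diamonds mark WT 3 and IRF4 KO 1. Acta2, Tagln, Smtn, Klf4 and Tnf sit in tight groups per genotype, whereas Mki67 and Cd68 are high in WT 3 and IRF4 KO 1.

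Inflammatory genes formed the list with the smallest p. In the inflammatory cytokine and adhesion list, 7 of 22 genes passed adjusted over the list alone, all higher in IRF4 KO, and 0 passed over all genes. Vcam1, an adhesion receptor for leukocytes, read 8.56 ± 0.13 in WT and 9.68 ± 0.08 in IRF4 KO. Nos2, the inducible nitric oxide synthase, was higher by 1.15, the monocyte chemokine gene Ccl2 by 1.11, and Ccl5, Il6 and Il1b by 1.08, 1.09 and 1.05. Ccl2 and Il6 read below 4.89 in both genotypes. Camera called the list up with a mean of 0.39 (adjusted p = 5.77e-11; 0.173 with an estimated correlation). The other 15 genes, left after the 7 were taken out for their p in this same comparison, had a mean of 0.048 (adjusted p = 0.484). The median SD within a genotype was 0.141 for the 7 genes and 0.340 for the other 15. The list mean was 0.36 between IRF4 KO 1 and WT 3 and 0.41 over the other 4 arrays.

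Genes of alternatively activated macrophages were lower on average. Arginase Arg1 (3.31 ± 0.07 in WT, 2.20 ± 0.10 in IRF4 KO), the chitinase-like Chil3 (3.77 ± 0.13 and 2.59 ± 0.09), the secreted factor Retnla (4.03 ± 0.18 and 2.96 ± 0.04) and the mannose receptor Mrc1 (4.22 ± 0.09 and 3.19 ± 0.10) were 4 of 14 genes that passed adjusted over the list alone. All 4 lay below the median gene level. The list mean was -0.23 and camera called it down (adjusted p = 0.0455; 0.797 with an estimated correlation), while its median was 0.040 and 9 of 14 genes were higher. Without the 4, taken out for their p in this same comparison, the mean of the other 10 was 0.12. The median SD within a genotype was 0.105 for the 4 and 0.314 for the other 10. The list mean was -0.079 between IRF4 KO 1 and WT 3 and -0.30 over the other 4 arrays, and with the spike-in block the adjusted p was 0.0924. The call also ended without WT 1 (0.0572), WT 3 (0.210), IRF4 KO 2 (0.228) or IRF4 KO 3 (0.114).

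Matrix and synthetic smooth muscle genes were higher in 19 of 22 cases. Mmp2, a gelatinase, read 7.87 ± 0.19 in WT and 9.11 ± 0.18 in IRF4 KO and was the 1 gene that passed adjusted over the list alone. The proteoglycan Bgn read 12.98 ± 0.29 and 13.25 ± 0.03, the matricellular Postn 11.89 ± 0.24 and 12.15 ± 0.13, and Thbs1 6.42 ± 1.99 and 8.06 ± 1.75. On its other probe set Thbs1 differed by 0.076. Camera called the list up with a mean of 0.33 (adjusted p = 0.00383; 0.797 with an estimated correlation). The mean was 0.38 between IRF4 KO 1 and WT 3 and 0.31 over the other 4 arrays. Without IRF4 KO 1 it turned to -0.23 (adjusted p = 0.898), and the call ended without WT 1 (0.483) or WT 2 (0.131).

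Interferon-stimulated genes were higher in 17 of 24 cases with a mean of 0.20 (camera adjusted p = 0.00383; 0.797 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The antiviral gene Rsad2 read 4.42 ± 0.15 in WT and 4.98 ± 0.28 in IRF4 KO, Rtp4 4.62 ± 0.82 and 5.62 ± 0.34, Ifit3 4.92 ± 0.38 and 5.74 ± 0.98, and the GTPase gene Gbp2 8.52 ± 1.21 and 7.41 ± 0.32. On their other probe sets Rsad2 differed by 0.0078 and 0.11, Rtp4 by -0.24 and Gbp2 by -0.75. The list mean was 0.47 between IRF4 KO 1 and WT 3 and 0.058 over the other 4 arrays (adjusted p = 0.162). The call ended without IRF4 KO 1 (0.374).

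The other lists of regulators were not called over the 6 arrays. In the proliferation list 16 of 24 genes were higher, and only Pcna passed adjusted over the list alone. Mcm2 read 6.11 ± 0.15 in WT and 5.96 ± 0.17 in IRF4 KO, Mcm4 6.24 ± 0.07 and 5.79 ± 0.64, and Tk1 3.53 ± 0.52 and 3.99 ± 1.16 (camera adjusted p = 0.206). The list mean of 0.093 moved to 0.39 without WT 3 (0.00105), 0.32 without IRF4 KO 2 (0.00358) and 0.27 without IRF4 KO 3 (0.0155), where it was called, and to -0.32 without IRF4 KO 1 (0.0687), -0.10 without WT 2 (0.983) and -0.012 without WT 1 (0.607). In the growth arrest list 13 of 18 genes were lower, and Cdkn1a passed over the list alone. Gadd45b, a stress-response gene, read 7.40 ± 0.20 and 6.39 ± 0.50, but differed by only -0.29 and -0.33 on its other probe sets. The growth arrest list was not called (camera adjusted p = 0.119), but was called down without IRF4 KO 1 (0.0238) or WT 1 (0.0301). In the KLF family 8 of 13 genes were lower and Klf4 passed over the list alone (0.126; called down without IRF4 KO 2, 0.0439). Klf15 read 7.17 ± 0.13 and 6.92 ± 0.11, and Klf7 7.94 ± 0.14 and 7.61 ± 0.41. Of 7 measured relatives of Irf4, 3 were higher (0.722), with Irf8 at 4.04 ± 0.36 and 4.49 ± 0.54.

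Lists of other cell types were tested as levels of marker genes, and none of the 16 passed camera over all genes and all 6 arrays. With dim genes left out, T cells and endothelium (both 0.0152) and skeletal muscle (0.0349) were called up and antigen presentation down (mean -1.10, adjusted p = 0.0179) over the 6 arrays, and with quantile normalization endothelium was called up (0.0277). An estimated correlation was not used in those fits. With all genes kept, it gave these lists adjusted p values of 0.797 to 0.972. At the preset correlation, the lowest adjusted p values were 0.061 for B cells and 0.0837 for T cells, endothelium and skeletal muscle. Peripheral nerve followed at 0.117, and all of these are over all genes. In the adipocyte list (0.733), Pparg, the master regulator of fat cells, passed adjusted over the list alone at 4.58 ± 0.11 in WT and 3.49 ± 0.03 in IRF4 KO, whereas the fat cell gene Fabp4 read 9.60 ± 0.29 and 9.31 ± 0.44. Adjusted p values were 0.563 for macrophages and lymphatics, 0.843 for neutrophils, mast cells and antigen presentation, and 0.278 for adventitial fibroblasts. They were 0.375 for plasma cells and thyroid, and 0.938 for cartilage and red blood cells. Leaving out 1 array called 9 of the 16 lists at least once. Without IRF4 KO 2 these were B cells (0.0384), T cells (0.0132), fibroblasts (0.0352), endothelium (0.0439), nerve (0.0401) and macrophages (0.00605), all up. Without WT 3 they were T cells (0.0435), endothelium (0.00209), nerve and cartilage (both 0.0282) and macrophages (0.00884), and without IRF4 KO 3 endothelium (0.00260) and macrophages (0.0311), all up. Without IRF4 KO 1, B cells were up (0.0414), and macrophages (1.39e-05), antigen presentation (0.000125) and cartilage (0.0446) were down. Without WT 1, B cells (0.0243) and skeletal muscle (0.0250) were up. The immediate early and heat shock list, a sign of tissue handling, gave 0.938. Within it Egr1 read 9.92 ± 0.42 and 10.82 ± 0.63, Fos 10.12 ± 0.56 and 10.93 ± 0.68, and Dnajb1 9.14 ± 0.37 and 8.32 ± 0.26. Dnajb1 differed by -0.030 on its other probe set.

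WT 3 and IRF4 KO 1 stood apart from the other 4 arrays, and several lists moved with them. Their mean macrophage list levels, relative to the mean of all arrays, were 1.37 and 2.37, against -1.26 to -0.47 elsewhere. The cartilage list was at 1.82 and 1.92 against -1.09 to -0.74, the matrix list at 0.90 and 1.28 against -0.76 to -0.34, and the proliferation list at 0.55 and 0.87 against -0.43 to -0.26. Col2a1, the collagen of cartilage, read 12.1 and 12.2 in WT 3 and IRF4 KO 1 and 3.75 to 5.15 in the others. The lysosomal protease gene Ctss read 8.87 and 11.1, against 4.93 to 7.45. The first principal component held 57.1% of the variance, with scores of 46.1 and 49.6 for these arrays and -43.9 to -9.75 for the others. Poly-A spike-in controls averaged 4.93 and 5.14 in these arrays and 7.35 to 9.26 in the others.

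**Figure D2:**
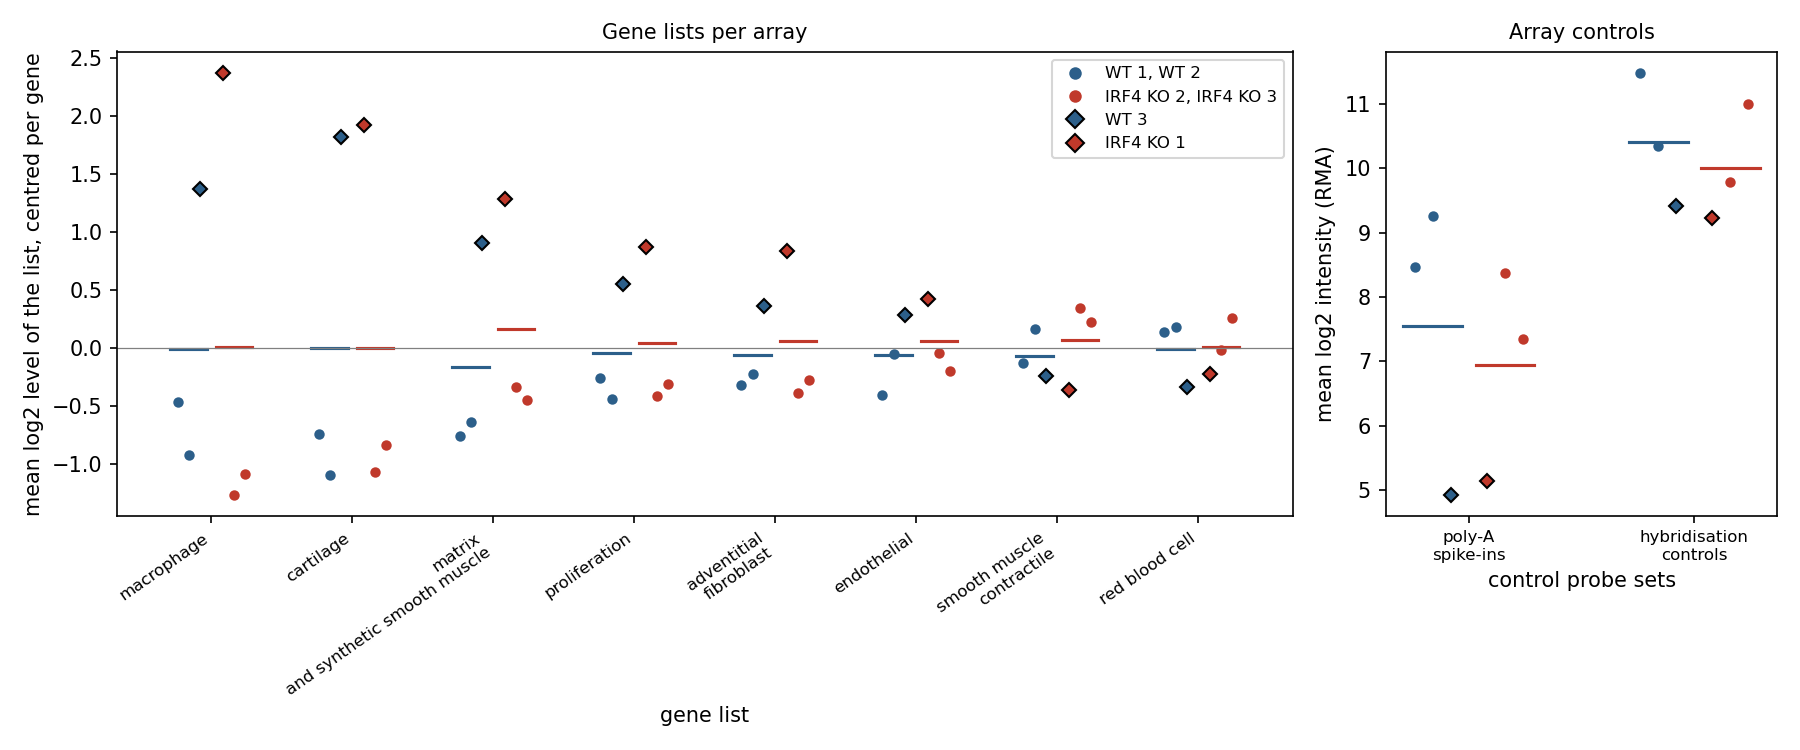
Left, mean log2 level of 8 gene lists per array, each gene centred on its mean over 6 arrays; right, mean log2 intensity of poly-A spike-in and hybridisation controls per array. Points are arrays, bars are means of 3 arrays, blue is WT, red is IRF4 KO, and outlined diamonds mark WT 3 and IRF4 KO 1, which lie highest for macrophage (1.37 and 2.37) and cartilage genes (1.82 and 1.92) and lowest for poly-A controls (4.93 and 5.14).

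Each set of arrays with like spike-in levels held both genotypes, so the comparison was repeated within them. With the spike-in level as a block, 0 genes passed (smallest adjusted p = 0.0904). Camera called 3 lists: inflammatory cytokines and adhesion (1.10e-08), matrix (2.43e-07) and interferon-stimulated genes (5.12e-05). With an estimated correlation 0 lists passed in that fit, and these 3 gave 0.292, 0.292 and 0.415. The contractile list did not pass with the block (0.101). Klf4 differed by -1.05 between IRF4 KO 1 and WT 3 and by -1.19 among the other 4 arrays, and Acta2 by 1.22 and 1.09. Without WT 3 and IRF4 KO 1, 5 genes passed with limma, all lower in IRF4 KO: H2-Aa (-3.06, adjusted p = 0.00417), H2-Ab1 (-3.30, 0.00627), H2-Eb1 (-2.75, 0.00192), H2-DMa (-2.62, 0.00174) and Cd74 (-2.37, 0.00418). These genes encode MHC class II molecules and proteins that load them with peptide. Camera called 8 lists over those 4 arrays, among them antigen presentation (mean -0.94, adjusted p = 2.82e-07) and macrophages (-0.48, 1.11e-05), both lower in IRF4 KO. Between IRF4 KO 1 and WT 3 both lists went the other way, by 0.57 and 1.01. The immediate early and heat shock list (0.29, 0.00925), a sign of tissue handling, and the peripheral nerve list (0.26, 0.0394) were called up over the same 4 arrays, with Egr1 higher by 1.45 and Fos by 1.33. Between IRF4 KO 1 and WT 3 the immediate early list went the other way (-0.55), as did Egr1 (-0.22) and Fos (-0.22). The nerve list differed by 0.016 in that pair. The other lists called up over the 4 arrays were inflammatory (0.41, 2.04e-07), matrix (0.31, 8.33e-05) and contractile genes (0.26, 0.000596). Alternative macrophage genes were called down (-0.30, 0.0110). With an estimated correlation, 0 lists passed over the 4 arrays. The adjusted p was then 0.672 for antigen presentation, macrophages and immediate early genes, and 0.795 for peripheral nerve. It was 0.672 for inflammatory, matrix and alternative macrophage genes, and 0.830 for contractile genes. Over all genes and the 6 arrays, these 5 genes and the lists of antigen presentation, macrophages, immediate early genes and nerve did not pass, while antigen presentation did with dim genes left out (mean -1.10, adjusted p = 0.0179). IRF4 KO 1 was above every WT array for H2-Aa (10.96, against 10.11 to 10.28).

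**Figure D3:**
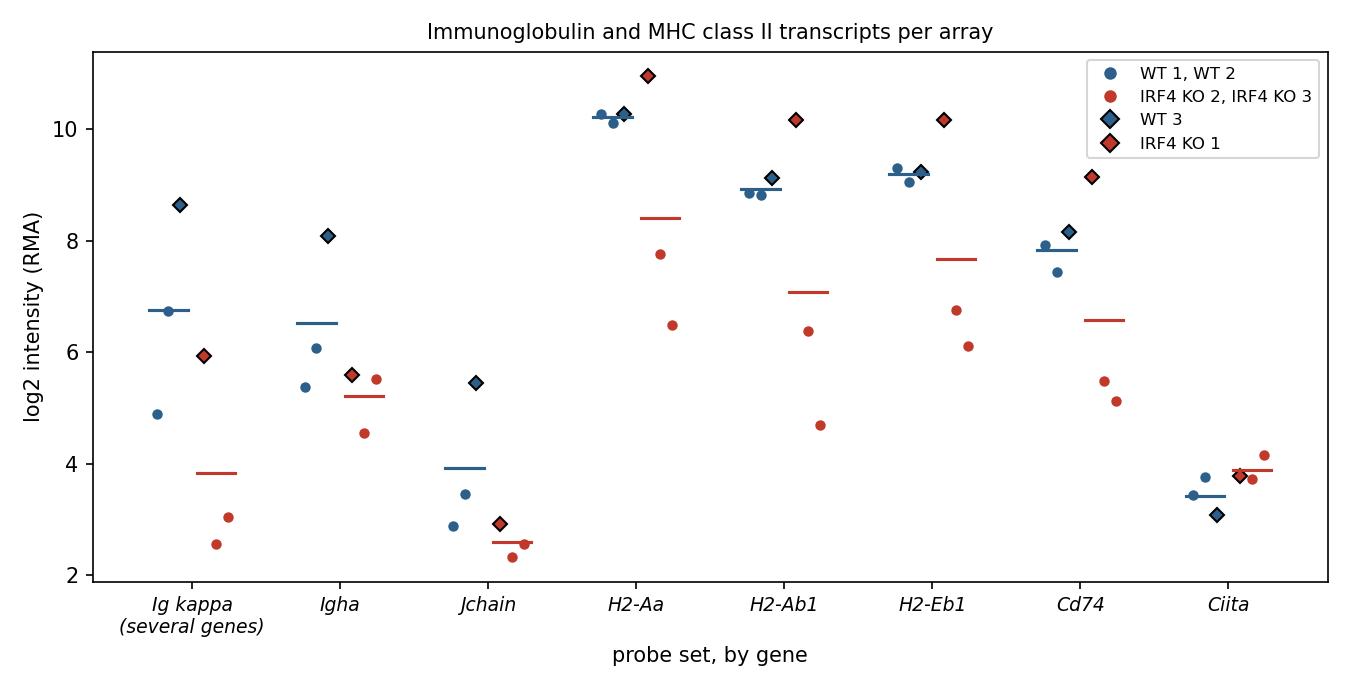
Log2 intensity per array (y axis) of 1 probe set each for immunoglobulin and MHC class II genes and the MHC class II transactivator Ciita (x axis); points are arrays, bars are means of 3 arrays, blue is WT, red is IRF4 KO, and outlined diamonds mark WT 3 and IRF4 KO 1. For H2-Aa, IRF4 KO 1 is at 10.96, above the WT arrays at 10.11 to 10.28, and IRF4 KO 2 and 3 are at 7.76 and 6.49.

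A knockout allele can carry flanking DNA of another strain, so the neighbours of Irf4 were compared with other genes. Of 246 genes within 20 Mb of Irf4, 0 passed the limma threshold and 4 had an unadjusted p under 0.05 (Agtr1a, Gcnt2, Prpf4b and Tmem170b, named after their values were seen). That share was 1.63%, against 1.49% of the other genes (Fisher's exact test, two-sided, p = 0.788). Within 5 Mb, 2 of 67 genes did so, Agtr1a and Prpf4b (Fisher's exact test p = 0.263).

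Sex-linked transcripts were read as values. Eif2s3y, encoded on the Y chromosome, lay between 6.98 and 8.24 in all 6 arrays, and Kdm5d between 4.47 and 6.31. Uty read 3.99 to 5.05, and Ddx3y was not read here. Xist, the transcript of the inactive X chromosome, read 8.24 in WT 3 and 3.75 to 4.67 in the other 5 arrays. WT 3 was also highest on the further Xist probe sets (4.79 and 3.67). Eif2s3y was high in WT 3 as well (8.24), as a pool of both sexes would give, but no label gives sex. Whether sex bears on other genes that are highest in WT 3 was not tested.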

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

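The settings with a spike-in block, without the low spike-in arrays, without genes under p 0.001, on all probe sets, and fry for the count of lists were chosen after seeing the data. Genes past the threshold stayed at 0 in 15 of 18 alternatives, each single array left out included (0 to 0). They were 68 with array weights, 36 at unadjusted p under 0.05 with a log2 change over 1, and 5 without the low spike-in arrays. The array weights gave IRF4 KO 2 a weight of 26.7 and every other array at most 2.57, and their estimation stopped without converging, so that fit rests on 1 array and its calls are not relied on; it also called 1 gene near Irf4, against 0 in the other 15 alternatives. The Irf4 change stayed uncalled in all 14 alternatives it could be computed in, from -0.19 to 0.09 without single arrays; the filter on dim genes removed it.

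Gene lists past the threshold were 3 with array medians subtracted, 3 with the spike-in block, 8 without the low spike-in arrays, 1 without genes under p 0.001, 0 with an estimated correlation and 0 with fry, and 4 to 11 without single arrays (8 without IRF4 KO 1, 11 without IRF4 KO 2, 9 without WT 3). The fry count is of its test for a shift in 1 direction. Its mixed test, which counts changes either way, passed 5 lists. These were contractile (fry mixed adjusted p = 0.000141), inflammatory (0.000108), alternative macrophage (4.27e-07), KLF (0.00245) and adipocyte genes (0.000240). Each of them holds at least 1 gene with p under 0.001. The numbers do not pair the arrays (correlations of same-numbered deviations -0.52, 0.37 and -0.62; only WT 2 and IRF4 KO 2 correlated best with their own number): with the replicate block 4 lists and 0 genes passed. The alternative macrophage list, at -0.23 with the block, then missed the threshold (adjusted p = 0.0643).

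List means that lost their call were as follows, the cause not tested. All 5 did so with an estimated correlation and with fry, which leave the means as they are: 0.39 for inflammatory, 0.33 for matrix, 0.20 for interferon, 0.14 for contractile and -0.23 for alternative macrophage genes. Without genes under p 0.001 the means were 0.048 (inflammatory), 0.29 (matrix), -0.026 (contractile) and, reversed, 0.12 (alternative macrophage), because their called members were left out; the interferon list has no such member, so that setting does not test its call. With array medians subtracted contractile (0.10) and alternative macrophage (-0.26) did so, with the mean of all probe sets alternative macrophage (-0.21), with the filter on dim genes interferon (0.077), with array weights matrix (0.13), with the spike-in block contractile (0.14) and alternative macrophage (-0.23), and without the low spike-in arrays interferon (0.058). Lists that gained a call over the 6 arrays were T cell (0.27), endothelial (0.11), skeletal muscle (0.30) and antigen presentation (-1.10) with the filter on dim genes, 7 lists then passing, and endothelial (0.16) with quantile normalization, 6 then passing. Without the low spike-in arrays the macrophage list (-0.48, from 0.016) reversed and was called. For the immediate early list the mean kept its sign (0.29, from 0.0092), while the direction of the camera test turned from down to up and it was called. Without single arrays the ranges were -0.38 to -0.14 for alternative macrophage, 0.020 to 0.32 for interferon, -0.23 to 0.86 for matrix, -0.0019 to 0.35 for contractile, 0.31 to 0.49 for inflammatory, -0.95 to 0.92 for cartilage and -1.17 to 0.70 for macrophage. Of the named genes other than Irf4, 28 values came past the threshold, all with array weights or without the low spike-in arrays, and none was called otherwise. Another 36 uncalled values of named genes moved by at least their SD within a genotype: 17 with array weights (4 with the sign changed), 15 with the mean of all probe sets (1 with the sign changed) and 4 without the low spike-in arrays. Low signal, below the median gene level, limits Irf4, Ccl2, Il6, Arg1, Chil3, Retnla and Mrc1.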

Other observations

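The plasma cell list, the Irf4 change, the genes near Irf4 and leaving out single arrays were planned; the other tests here, and the use of the planned ones to weigh explanations, were chosen after the results they bear on were seen. Immunoglobulin transcripts read lower on average in IRF4 KO on several probe sets, but none passed after adjustment over all probe sets. The plasma cell and immunoglobulin list was not called (mean -0.22, adjusted p = 0.375), and its mean was 0.037 without WT 3. Across 3 probe sets that each match several immunoglobulin kappa genes, the log2 changes were -2.91, -2.45 and -1.95 (limma unadjusted p = 0.0271, 0.0320 and 0.0381). With the spike-in level as a block, the unadjusted p values were 4.59e-05, 5.42e-05 and 0.000194 and the adjusted ones 0.168, 0.168 and 0.198. These probe sets differed by -2.70, -2.88 and -3.07 between IRF4 KO 1 and WT 3 and by -3.01, -2.23 and -1.39 among the other 4 arrays. Jchain, which joins secreted antibodies, read 3.93 ± 1.35 in WT and 2.59 ± 0.30 in IRF4 KO, and the first of 3 Igha probe sets 6.51 ± 1.40 and 5.22 ± 0.58 (SD, n = 3). WT 3 was highest for each, with 8.63 on the first kappa probe set and 5.45 for Jchain. Jchain differed by -2.54 between IRF4 KO 1 and WT 3 and by -0.73 among the other 4 arrays, and that Igha probe set by -2.49 and -0.70. The plasma cell gene Mzb1 read 4.82 ± 0.21 in WT and 4.70 ± 0.13 in IRF4 KO. Tnfrsf17 (2.47 ± 0.15 and 2.81 ± 0.46) and Pou2af1 (2.05 ± 0.09 and 2.03 ± 0.04) were too dim in both genotypes to show a fall. IRF4 is needed for plasma cells to form, as textbook background.

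MHC class II transcripts split the IRF4 KO arrays. H2-Aa read 10.96 in IRF4 KO 1 and 7.76 and 6.49 in IRF4 KO 2 and 3, against 10.22 ± 0.09 in WT. H2-Eb1 read 10.17, 6.75 and 6.11, against 9.20 ± 0.12, and Cd74 read 9.15, 5.48 and 5.12, against 7.83 ± 0.37. Their transactivator Ciita read 3.42 ± 0.34 in WT and 3.89 ± 0.24 in IRF4 KO. In IRF4 KO 1 the macrophage list was also at its highest, 2.37, and in IRF4 KO 2 and 3 at its lowest, -1.26 and -1.08. IRF4 KO 1 thus read like WT or above it for H2-Aa, H2-Eb1 and Cd74. It read with IRF4 KO 2 and 3 for Klf4 (6.95, 6.75 and 6.91, against 7.92 to 8.11 in WT) and for Nnt on both brighter probe sets (7.47, 7.84 and 7.30, against 8.76 to 9.36, and 7.14, 7.17 and 6.92, against 8.21 to 8.77). On the first kappa probe set it read 5.93, which is 2.70 below WT 3, its partner in spike-in level, but above WT 1 (4.88) and IRF4 KO 2 and 3 (2.55 and 3.03), and it was above WT 1 on the other two kappa probe sets as well. Klf4 and Nnt rank high because the labels part them, so they are no independent check of its genotype label, which stays open. Every IRF4 KO mean over 3 arrays rests on that label; without IRF4 KO 1, 0 genes and 8 lists passed.

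The first pattern is the set of 26 genes with p under 0.001, of which 18 belong to the 165 measured genes of the pathway and regulator lists; 3 of the next 100 genes in rank do. For the 11 genes that have another probe set, a pick of single probe sets with small spread is argued against: of their 15 other probe sets, which the ranking did not use, 86.7% shifted the same way by at least 50% of the change of the probe set used, against 15.3% of 144 such probe sets of the next 100 genes (Fisher's exact test p = 2.84e-08). The 2 that did not follow, of Nnt and Tesc, were dim (means 2.59 and 2.32). Above the median level of all probe sets, 11 of 11 shifted so, against 14 of 57 (Fisher's exact test p = 2.91e-06). Both tests count probe sets of the same gene as independent, which they are not, so these p values are likely too small. The other 15 of the 26 genes have 1 probe set each, so for them such a pick stays open. The within-genotype SD of the 15 other probe sets of the 11 genes lay at a median percentile of 2.4 among 500 probe sets of like mean, against 52.8 for the next 100 genes. Low percentiles are what a step before deposit that set values apart from the arrays' common variation would give. The sources used here do not describe such a step. The percentiles were not low for every gene, with 27.2 and 93.8 for Nnt, 54 for Rab4a and 19.6 for Cd86. On the probe sets used for the genes the percentile was 44.2 for Nnt and 7.4 for Rab4a. Nnt thus varied like other genes, so that reading does not cover it. For Rab4a the probe sets differ, and the reading stays open. A shared response to loss of IRF4 stays open. The Irf4 probe sets were dim and alike in both genotypes (change -0.065). No background level was computed and the deleted part is not given, so whether they could show a loss is not known. They do not decide whether there is such a response. Such a response would not by itself explain the small spread of most of these genes. Nor would it explain changes of like size at mean levels from 2.46 to 13.3.

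Among the 10 ways to split the 6 arrays 3 against 3, the genotype split gave 26 genes with p under 0.001 and the highest of the others (WT 1, WT 3 and IRF4 KO 1 on one side) gave 25; the real count was reached by 1 of the 10, with the real one included. Splits that kept WT 3 and IRF4 KO 1 on one side gave 25, 3, 20 and 20 genes with p under 0.001. The other splits that parted these 2 arrays, as the genotype split does, gave 2, 1, 0, 0 and 6. For genes past the adjusted threshold the real count was 0, reached by all 10, and the highest other was 1. For gene lists the real count was 5, reached by 6 of the 10, and the highest other was 12. Splits that kept WT 3 and IRF4 KO 1 on one side gave 8, 12, 6 and 7 lists, and the other splits that parted them gave 4, 3, 0, 1 and 8; with the spike-in block 3 lists passed. With 10 splits no share can be under 0.05.

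The second pattern is the separation of WT 3 and IRF4 KO 1. A separate labelling run may account for part of it, since poly-A spike-ins in both lay at least 2.20 log2 units below every other array. The cartilage genes argue against it as the only cause. Of the 12 list members, 8 were higher in both arrays by over 1 log2 unit than in each other array. Col2a1 read 12.1 and 12.2, against at most 5.15. Hybridisation controls, added after labelling, were also lowest in both (9.41 and 9.22, against 9.78 to 11.48), so which step differed stays open. Other tissue in the pooled vessels may account for it too: the cartilage list lay 2.57 higher in both than in any other array, with 9 of its 12 members higher in both and 2 of the 12 above the median gene level elsewhere. Skeletal muscle, nerve and thyroid lists were not higher in both (gaps of -0.37, -0.01 and -0.47). Adventitial fibroblast and endothelial lists were, by smaller gaps of 0.59 and 0.34. A cartilage-like change of the injured wall and a differing macrophage content were not tested as causes, and these explanations can hold together.

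The third pattern is Nnt, lower by 1.55 in IRF4 KO on the probe set used and by 1.33 on another, and by 0.09 on a dim one (2.63 in WT). A common laboratory strain lacks part of this gene, so a candidate explanation is a differing genetic background. Nnt had a limma unadjusted p of 1.5e-04 but was not among the 4 genes within 20 Mb of Irf4 with p under 0.05. Nnt therefore lies outside that window. Genes near Irf4 did not differ from others (Fisher's exact test p = 0.788), but that test does not bear on Nnt. It also cannot exclude another background around the knockout allele, since most strain variants leave expression as it is. No label gives the strains.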
